A study of Homo sapiens with 8 samples.

How the data were processed

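HepG2 is an established human cell line derived from a liver tumour. Benzo[a]pyrene (BaP) is a polycyclic aromatic hydrocarbon that cells oxidise to DNA-binding metabolites. Per the labels, cells received medium with BaP or with a solvent, and the 4 groups are BaP for 12 h, dimethyl sulfoxide (DMSO) for 12 h, BaP for 24 h and DMSO for 24 h, with 2 arrays each. The treatment protocol gives the DMSO solvent as 0.5%; the labels used here state no dose of BaP. Biotin-labelled cRNA was prepared from 250 ng total RNA with a 3' in vitro transcription kit and read on Affymetrix arrays, per the labels' protocols. The titles call the 2 arrays of a group biological replicates.

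The deposited expression values are on the log2 scale, and the authors made them with RMA in R 2.12.2, per the submitters' processing notes. RMA corrects background, gives every array the same distribution of probe intensities and summarises probes to 1 value per probe set, so a shift shared by all transcripts of an array is removed. The table holds 19064 probe sets, of which 19002 carry an Ensembl gene ID and 62 are Affymetrix controls. How probes were assigned to genes, and on which genome build, is not given in the sources used here. The authors' deposited table holds a second copy of the same values, log2 differences of BaP minus DMSO at each time, and limma p-values without adjustment, with Bonferroni adjustment and as a false discovery rate, per the file headers. Arrays carry no count depth, so their number, 2 per group, limits the precision. The control probe sets for a tryptophan synthesis transcript of Bacillus subtilis, read here as a control not added to the samples, reached 4.35 on the log2 scale, and 3153 of the 19002 genes had a mean at or below that level.

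The files do not pair the Ensembl IDs with gene names, and 0 of the 19002 IDs were found in the gene table used here. Genes are therefore given by ID, at most 2 that rose and 2 that fell. The rule written before the data were examined named, at each time, the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold whose 2 BaP arrays lay on one side of both DMSO arrays, 10 genes given by symbol, the leading members of gene lists given by symbol, and the 6 highest and 6 lowest genes of the other comparisons. The parts that need symbols could not be applied, and the gene lists could not be tested. The 4 IDs printed are the 2 highest and the lowest at 12 h and the lowest at 24 h. That choice within the rule was made after the values were seen. Values of the other genes are summarised as ranges.

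A limma model (version 3.58.1, R 4.3.3) with a mean per group was fitted to all 8 arrays, which left 4 residual degrees of freedom, with empirical Bayes moderation. Contrasts were BaP minus DMSO at 12 h and at 24 h, the difference between these effects, and DMSO at 24 h minus DMSO at 12 h. A second model with terms for time and compound gave the BaP effect over both times with 5 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 19002 genes within each of the 5 comparisons, and genes with an adjusted p under 0.05 were counted as changed. No filter on dim genes was used, and each gene had 1 probe set. Errors of log2 fold changes are limma's moderated standard errors. The control probe sets were tested in a fit of all 19064 probe sets. Refitting the authors' table in that way gave p-values that differed from the authors' by at most 0.00203 on the log10 scale.

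The model was tested on simulated data for the comparison at 12 h, with 200 of 19002 genes changed and gene variances drawn from the fitted prior. It recovered 55.2% of genes changed 1.41-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold, with 9 false calls among 175. The simulated errors were independent and followed the model's own assumptions, so a low share of false calls was built in. They held no array-wide error, replicate effect or trend of the variance with level. Fewer genes were changed than the 1571 called at 12 h, and no change below 1.41-fold was simulated. Recovery at the median sizes called at 12 h, 0.43 and -0.47 on the log2 scale, is therefore not known.

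After the data were examined, cell cycle gene sets were added, because they can be matched by Ensembl ID. They come from a table of human cell cycle marker pairs installed with the R package scran. A gene entered the set of a phase if it was the leading gene in at least 90% of at least 10 of its pairs for that phase. The sets were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Alternatives for the gene counts and named genes were the replicate number as a block, each array left out, the arrays of 1 time alone, cyclic loess, median centring, 2 filters on dim genes, trended or robust moderation, array weights, a stricter threshold, a minimum fold of 1.5, the authors' deposited table and the second copy of the values. The arrays of 1 time and the deposited table give no difference between times and no DMSO comparison. The cell cycle sets were not recomputed with other moderation, array weights, a stricter threshold, a minimum fold, the deposited table or the second copy, nor the 28S probe set with the filters or the last 4 of these. Genes leading at least 80% of pairs and camera on ranks were further alternatives for the sets. Scaling each array to its poly-A controls was added after the data were examined.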

Results

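Transcript levels were measured in HepG2 cells exposed to BaP or to the solvent DMSO for 12 h or 24 h, with 2 arrays in each of 4 groups. The series asked how the transcriptome of these cells responds to BaP at 2 times. Array medians lay between 6.64 and 6.68 on the log2 scale. Replicate arrays of a group correlated at 0.998 across genes in every group, and the median absolute difference between them ranged from 0.0773 to 0.0964. In a principal component analysis of all 19002 genes, component 1 held 43.3% and component 2 held 27.0% of the variance. Both BaP arrays at 12 h lay at the negative end of component 1, at -23.3 and -23.4, and both BaP arrays at 24 h at the positive end of component 2, at 16.5 and 18.7.

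**Figure D1:**
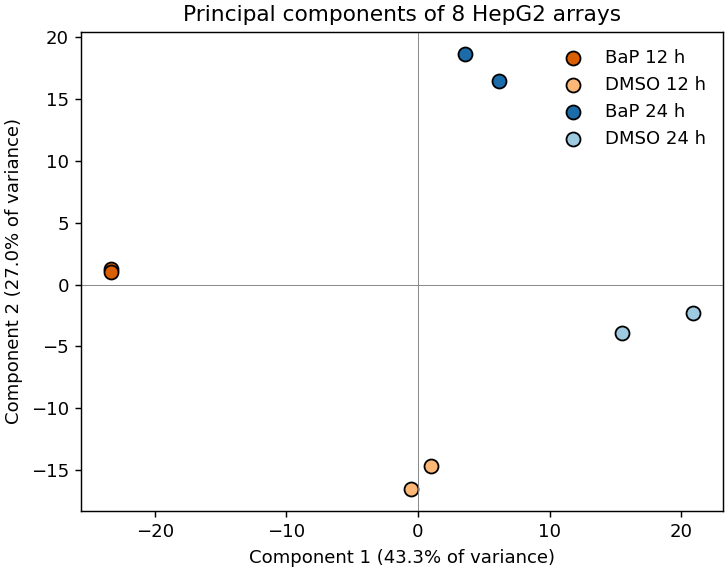
Each point is 1 of the 8 arrays, placed by its scores on the first and second principal components of 19002 genes, with colours for the 4 groups of 2. The BaP arrays at 12 h lie at -23.3 and -23.4 on component 1, and the DMSO arrays at 12 h at -14.7 and -16.5 on component 2.

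The first comparison asked which transcripts BaP changed after 12 h. ENSG00000140465 rose most, from 6.70 ± 0.18 in DMSO to 13.25 ± 0.00036 in BaP (log2, mean ± SD, n = 2). This was a 93.8-fold increase, with a log2 fold change of 6.55 ± 0.10 (SE) and an adjusted p of 1.29e-08 in limma. ENSG00000108602 rose 6.28-fold, with a log2 fold change of 2.65 ± 0.19 (SE, adjusted p = 1.03e-04). Among the 10 genes that rose most, log2 fold changes ranged from 1.76 to 6.55. ENSG00000173482 fell most, from 9.67 ± 0.05 to 7.55 ± 0.17 (SD, n = 2), with a log2 fold change of -2.12 ± 0.11 (SE, adjusted p = 1.53e-05). The 10 genes that fell most had log2 fold changes from -2.12 to -1.79. In all, 1571 of 19002 genes changed at 12 h, 645 higher and 926 lower in BaP. Most changes were small, with a median of 0.43 for the genes that rose and -0.47 for those that fell. At least 2-fold changes were found for 48 genes that rose and 75 that fell. In each of the 1571 genes both BaP arrays lay on one side of both DMSO arrays, which held for 54.1% of all genes and is expected by chance for 33.3%. With 2 arrays per group the call itself favours such genes, so this is no separate support for the calls. Calls were more frequent among brighter genes, at 1.97% of the lowest, 8.95% of the middle and 13.9% of the highest level class, each of 6334 genes. The count depended on each array of that time: without BaP replicate 1 or 2 it was 708 or 679, and without DMSO replicate 1 or 2 it was 743 or 614. With arrays scaled to their poly-A controls, a scaling chosen after the data were seen that raised the median of all genes to 0.47, 1951 genes were higher and 60 lower.

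The second comparison asked which transcripts BaP changed after 24 h. ENSG00000140465 was again the gene that rose most, from 5.93 ± 0.08 to 12.25 ± 0.14 (SD, n = 2). The increase was 79.8-fold, with a log2 fold change of 6.32 ± 0.10 (SE, adjusted p = 1.76e-08). ENSG00000108602 rose 6.17-fold, with a log2 fold change of 2.62 ± 0.19 (SE, adjusted p = 3.15e-04). ENSG00000123560 fell most, from 8.17 ± 0.50 to 5.87 ± 0.53 (SD, n = 2), with a log2 fold change of -2.30 ± 0.41 (SE, adjusted p = 0.0148). At 12 h the same gene had a log2 fold change of -1.70 ± 0.41 (SE, adjusted p = 0.0369). Replicate 1 lay above replicate 2 in all 4 groups (by 0.80 in BaP and 1.05 in DMSO at 12 h, and by 0.74 in BaP and 0.71 in DMSO at 24 h). In the model without replicate numbers the calls were lost, with no change of direction, when some arrays were left out: at 24 h without BaP replicate 2 (adjusted p = 0.106) or DMSO replicate 1 (0.0691), and at 12 h without BaP replicate 2 (0.198) or DMSO replicate 1 (0.187). In all, 1153 genes changed at 24 h, 565 higher and 588 lower in BaP, with median log2 fold changes of 0.45 and -0.44. At least 2-fold changes were found for 32 genes that rose and 18 that fell. The authors' deposited table, which tested all 19064 probe sets, lists 1571 probe sets at 12 h and 1144 at 24 h with a false discovery rate under 0.05. The count at 24 h was 507 without BaP replicate 1, 314 without BaP replicate 2, 396 without DMSO replicate 2 and 569 when the 4 arrays of that time were fitted alone. After poly-A scaling 33 genes were higher and 77 lower.

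**Figure D2:**
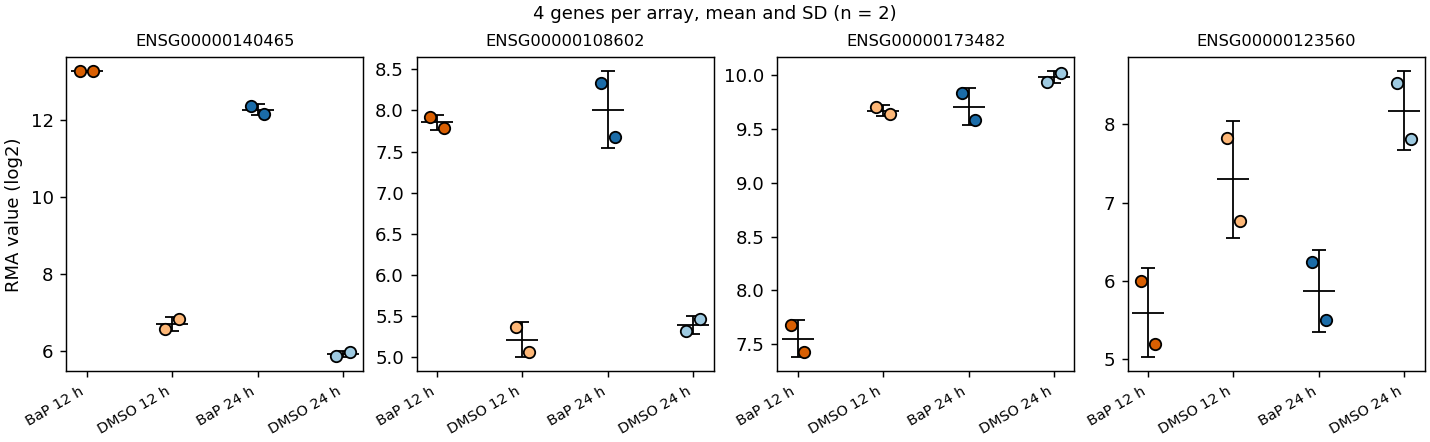
Each panel shows 1 gene, with its RMA value on the log2 scale for each of the 8 arrays (points) and the mean and SD of each group of 2 (bars). ENSG00000140465 lies above 12 in all BaP arrays and below 7 in all DMSO arrays, and ENSG00000173482 is low in the BaP arrays at 12 h alone.

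The effects at 12 h and 24 h, which share no array, were set side by side. Across the 19002 genes, the log2 fold changes correlated with a Pearson coefficient of 0.53 and a Spearman coefficient of 0.35; genes are not independent replicates. At both times 223 genes were higher and 283 lower in BaP, where 19.2 and 28.7 would be shared by independent lists. The lists are not independent, because both use 1 spread per gene from all 8 arrays and favour brighter genes. The expected numbers are therefore too low. With each time fitted alone, 312 genes changed in the same direction at both times. The sign was the same at both times in 61.6% of all genes. Of the 645 genes that rose at 12 h, 540 had a positive fold change at 24 h, and the median was 0.43 at 12 h and 0.21 at 24 h. Of the 926 that fell at 12 h, 777 had a negative fold change at 24 h (medians -0.47 and -0.21). Genes chosen at 24 h had smaller changes at 12 h in the same way: of the 565 that rose, 485 were positive at 12 h (medians 0.45 at 24 h and 0.23 at 12 h), and of the 588 that fell, 545 were negative (-0.44 and -0.30). Choosing genes at 1 time favours larger values at that time, so these medians do not show that the effect weakened. The 10 genes that rose most at 12 h and at 24 h shared 5 members, and the 10 that fell most shared 1. The number of genes changed in the same direction at both times, 506 in all, was 197 without BaP 24 h replicate 2, between 244 and 282 without any 1 of the other arrays except DMSO 24 h replicate 1 (386), and 50 after poly-A scaling (33 higher, 17 lower).

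**Figure D3:**
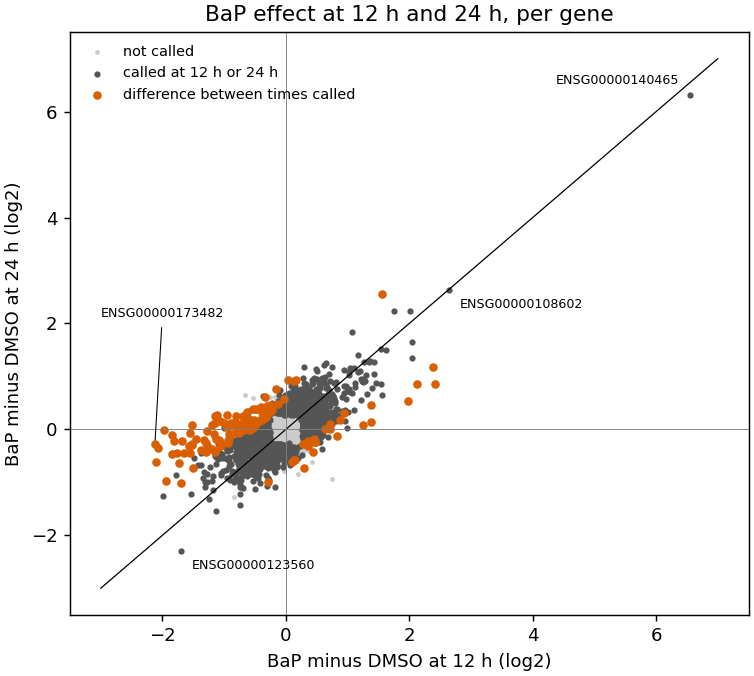
Each point is 1 of 19002 genes, with the log2 difference of BaP minus DMSO at 12 h on the horizontal axis and at 24 h on the vertical axis; the diagonal marks equal effects. The 122 genes in orange passed the test of the difference between times, and their median effect is -0.67 at 12 h and 0.03 at 24 h.

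The difference between these effects was then tested itself. ENSG00000173482, the gene that fell most at 12 h, had a log2 fold change of -0.27 ± 0.11 (SE, adjusted p = 0.188) at 24 h, and its effect was 1.85 ± 0.15 higher at 24 h than at 12 h (adjusted p = 0.00247). In all, 122 genes had an effect that differed, 97 with a higher value at 24 h and 25 with a lower one. Of the 97, 63 had fallen at 12 h and did not pass the threshold at 24 h, 16 fell at both times, 10 rose at 24 h alone and 7 fell at 12 h and rose at 24 h. The median effect of the 97 genes was -0.89 at 12 h and 0.04 at 24 h. Of the 25, 15 had risen at 12 h and did not pass the threshold at 24 h. The effect was larger in size at 12 h for 102 of the 122 genes. The 6 highest differences ranged from 1.59 to 1.97 and the 6 lowest from -1.56 to -1.16. The count was lower in every fit without 1 array, and 325 with a trended prior. After poly-A scaling it was 22 (1 higher, 21 lower), and the difference of ENSG00000173482 was 1.28 and no longer passed in limma (adjusted p = 0.0685). That scaling moves the difference of every gene by the same amount and gives all genes of an array the same error. The lost call is therefore no evidence on this gene. With this scaling included, its adjusted p ranged from 2.21e-04 to 0.0685 over all settings.

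Time in culture without BaP was measured in the DMSO groups. ENSG00000140465 was lower at 24 h than at 12 h in DMSO by a log2 change of -0.77 ± 0.10 in limma (SE, adjusted p = 0.00767). This change of a single gene was not recomputed under the alternatives. Between 12 h and 24 h 1302 genes changed in DMSO, 595 higher and 707 lower at 24 h. The 6 highest changes ranged from 1.52 to 3.08 and the 6 lowest from -1.12 to -0.84. The balance of directions was not stable. It was 721 higher and 486 lower after cyclic loess, 758 and 507 without DMSO 24 h replicate 1, 95 and 40 without DMSO 24 h replicate 2, 142 and 123 without DMSO 12 h replicate 1, and 35 and 4 without DMSO 12 h replicate 2. Poly-A scaling, which shifts all genes of an array alike, gave 15767 higher and 0 lower in limma (1 lower at an unadjusted p under 0.05) and raised the median of all genes to 0.63. The count fell to 39 without DMSO 12 h replicate 2, 265 without DMSO 12 h replicate 1, 135 without DMSO 24 h replicate 2 and 849 without either BaP array of 12 h.

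With time as a covariate, 4 BaP arrays were compared with 4 DMSO arrays. BaP changed 1884 genes, 843 higher and 1041 lower. ENSG00000140465 had a log2 fold change of 6.43 ± 0.08 (SE, adjusted p = 1.18e-10) and ENSG00000108602 of 2.64 ± 0.13 (adjusted p = 1.16e-05). ENSG00000173482, whose effect differed between times, had -1.20 ± 0.31 (adjusted p = 0.0377). The count was 1182 without BaP 12 h replicate 1, 1217 and 1232 without DMSO 12 h replicate 1 and 2, and 192 after poly-A scaling (137 higher, 55 lower).

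Control probe sets on the array gave values for a few named transcripts. GAPDH, a glycolytic enzyme, and beta-actin, a cytoskeletal protein, had log2 differences between -0.11 and 0.04 at both times, and none of their 6 probe sets passed the threshold. Their group means lay between 13.5 and 14.4, where the highest gene value of an array was between 14.79 and 14.87. Whether signal this near the top still follows the amount of transcript was not tested. The 4 probe sets of ISGF3A, an interferon signalling factor, had differences between -0.14 and 0.07 and did not pass either. Labelling used a 3' in vitro transcription kit, and whether the ribosomal RNA probe sets follow the amount of ribosomal RNA was not tested. The signal of a probe set from the middle of 28S ribosomal RNA was lower in BaP in limma at 12 h (-0.90, adjusted p = 2.35e-04) and at 24 h (-0.51, adjusted p = 0.00684). The call at 24 h was lost without BaP 24 h replicate 2 (adjusted p = 0.0560). A second 28S probe set, nearer the 5' end, passed at 12 h (-0.68) and not at 24 h (-0.04). The third, from the 3' end, had 0.08 at 12 h (adjusted p = 0.688) and -0.08 at 24 h (adjusted p = 0.709), and the difference between times did not pass for any of the 3 28S probe sets. The middle probe set kept its direction under cyclic loess, median centring and poly-A scaling, and after poly-A scaling its values were -0.45 at 12 h (adjusted p = 0.104) and -0.62 at 24 h (adjusted p = 0.489), neither past the threshold. The 24 probe sets of poly-A controls, Bacillus subtilis transcripts added to RNA before labelling in the standard Affymetrix procedure, were between -0.63 and -0.32 in BaP against DMSO at 12 h, where 2 passed the threshold. They lay between -0.79 and -0.45 in DMSO at 24 h against 12 h, where 11 passed. At 24 h their differences between BaP and DMSO ranged from -0.07 to 0.42 and none passed. The mean of the 18S ribosomal RNA probe sets was 11.3 on DMSO 24 h replicate 2 and between 12.6 and 13.1 on the other 7 arrays.

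**Figure D4:**
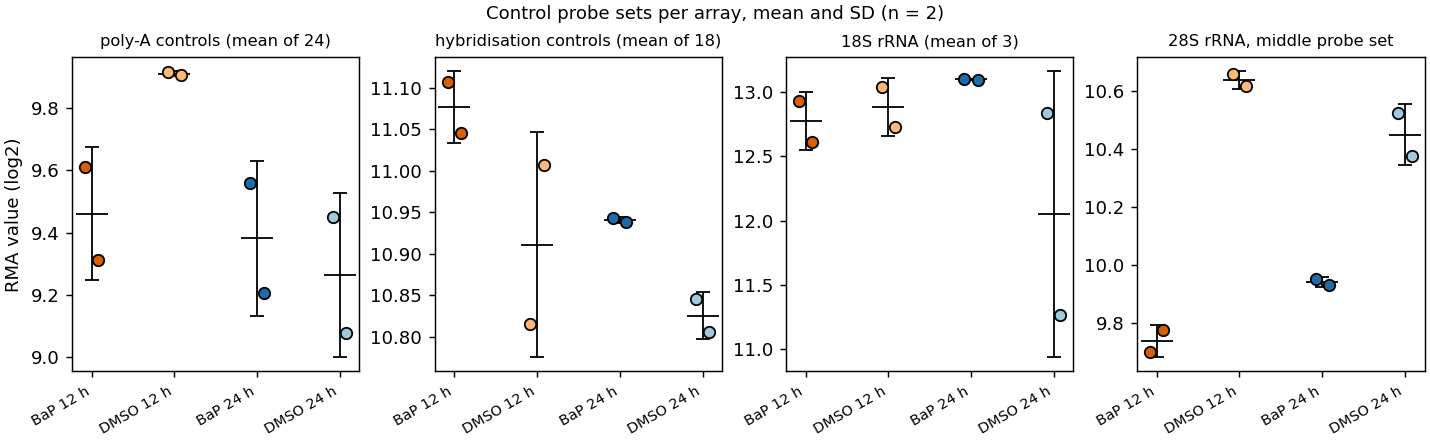
Each panel shows 1 family of control probe sets, with the RMA value on the log2 scale for each of the 8 arrays (points) and the mean and SD of each group of 2 (bars). The poly-A control mean is 9.91 in DMSO at 12 h and between 9.26 and 9.46 in the other groups, and the 18S mean of 1 DMSO array at 24 h is 11.3.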

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

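The fit without a single array was planned, but its use to judge that array as the whole source was chosen after the results had been seen. So were the test of drift in the DMSO arrays and scaling to the poly-A controls. The median over the 122 genes without that array and the test by cyclic loess were written down before. The effect of BaP differed between 12 h and 24 h, by a test of the difference itself, for 122 genes, and for ENSG00000173482 by 1.85 on the log2 scale. Of the 122, 63 had fallen at 12 h and did not pass the threshold at 24 h. A single array, DMSO 24 h replicate 2, which stands apart in its 18S signal, is argued against as the whole source. In a fit without it 45 genes passed, 42 of them higher at 24 h. The spread of its lone partner was taken from the other groups in that fit. Of the 45, 41 were among the 122. This overlap and the shared direction carry no separate weight, because both fits use all the other arrays. The median difference over the 122 genes without DMSO 24 h replicate 2, 1.02 times its value, carries no weight either. Those genes were chosen with the array in the fit. Drift of the solvent arrays would need the DMSO change to make up most of the difference, and its median share over the 122 genes was -0.0769. Those genes were chosen with the DMSO arrays in the fit, and a median does not exclude drift for single genes. Cyclic loess on top of the deposited normalization gave a median difference of 1.01 times its value. It was applied to values already normalized and read over the same 122 genes. It therefore cannot tell whether the deposited normalization is a source. The exposure time itself stays open, as a hypothesis found and tested on the same arrays: part of the early decrease under BaP may be transient. The tests above covered the DMSO arrays and the normalization, not the BaP arrays. Over the 97 genes with a higher effect at 24 h, the median change from 12 h to 24 h was 0.95 in BaP and 0.07 in DMSO. An error shared by both BaP arrays of 1 time was not tested and cannot be told apart from exposure time. A common shift of all transcripts, which the deposited normalization removes, also stays open. Scaling to the poly-A controls gives no evidence on it: it moves the difference of every gene by the same amount (median -0.58 after it), so the 1 higher and 21 lower genes it leaves follow from the shift, and replicates differed by up to 0.374 in their poly-A means.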

How the results depend on the processing

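Scaling to the poly-A controls, and every alternative for the 28S probe set, the cell cycle sets and the number of genes changed at both times, were chosen after the data were seen. Whether the replicate numbers pair arrays across groups is not settled: the labels do not say so, the authors' deposited table names replicate 1 Ex2 and replicate 2 Ex3 in all 4 groups without saying what that means, the replicate gap of ENSG00000123560 has the same sign in all 4 groups, and the deviations of equally numbered arrays correlated between 0.10 and 0.14 in 5 pairs of groups and at -0.05 between BaP and DMSO at 24 h. With the replicate block the counts were 1679 at 12 h, 1297 at 24 h, 151 for the difference, 1388 in DMSO, 1812 over both times and 548 at both times; with a block within each time they were 1298, 896, 85, 895, 1321 and 391, all within 1.5 times those reported. With 1 array left out, so that the spread of its lone partner was taken from the other groups, counts ranged from 614 to 1548 at 12 h, from 314 to 1000 at 24 h, from 31 to 88 for the difference, from 39 to 1265 in DMSO, from 1182 to 1572 over both times and from 197 to 386 at both times, and the correlation from 0.47 to 0.51. These fits have fewer arrays. At an adjusted p under 0.01 the counts were 658, 353, 31, 188, 702 and 166. With a minimum change of 1.5-fold they were 428 at 12 h, 292 at 24 h, 256 in DMSO, 269 over both times and 138 at both times. The arrays of 24 h fitted alone gave 569 genes, and those of each time alone 312 at both times. A trended prior gave 325 genes for the difference and 2015 in DMSO; the cause was not tested. Without the dimmest 30% of genes (13302 left) the difference held for 250 genes and the correlation was 0.57, and without genes under a mean of 5 (14112 left) for 220 with 0.56, with fewer genes tested. Poly-A scaling gave 2011 genes at 12 h, 110 at 24 h, 22 for the difference, 15767 in DMSO, 192 over both times and 50 at both times. It moved the median of all genes to 0.47, -0.11, -0.58, 0.63 and 0.18 in the first 5 of these. Every gene of an array then carries the same error of the 24 controls, so these counts do not rest on independent spreads. Other counts under cyclic loess, median centring, robust moderation, array weights, the authors' deposited table and the second copy stayed within 1.5 times. ENSG00000140465 and ENSG00000108602 kept their calls for BaP against DMSO at both times in all 24 settings. The settings counted here include the main fit and the second copy of the same values. For BaP against DMSO they also include the authors' fit of those values. These repeat the main result, and calls after poly-A scaling do not rest on independent spreads. The tallies of settings are therefore not counts of independent checks. ENSG00000173482 kept its call at 12 h in all 24 and its difference in 21 of 22. ENSG00000123560 kept its call in 20 of 24 settings at 12 h and 21 of 24 at 24 h, and had an adjusted p of 9.44e-05 and 1.10e-04 with the replicate block. None changed sign. The mean of probe sets per gene had nothing to average, and the planned gene lists and their alternatives were not run because the IDs could not be matched to symbols. In the dimmest level class 1.97% of genes passed at 12 h; whether low signal over background or fewer changes account for that was not tested.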

Other observations

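The cell cycle sets, the poly-A comparison and their tests were chosen after the data were seen; the count of splits was planned. Genes that lead the marker pairs of the G2 and mitosis phase were lower in BaP at both times by a test with a preset correlation, and not by one with an estimated correlation (adjusted p = 0.111 at 12 h and 0.183 at 24 h). Of 193 measured, 9 rose and 21 fell at 12 h, and 7 rose and 15 fell at 24 h, with median log2 fold changes of -0.04 at both times (camera with a preset correlation, adjusted p = 0.00708 and 0.00601). With fry, which tests the set against no change and not against other genes, the adjusted p was 0.00823 and 0.00865. The call at 24 h was also lost without DMSO 24 h replicate 2 (adjusted p = 0.154). After poly-A scaling the mean of this set at 12 h was 0.39, below the median of 0.47 over all genes, and the directions given here are relative to all genes. Of 200 S phase genes, 9 rose and 22 fell at 12 h (camera adjusted p = 0.0131; adjusted p = 0.111 with an estimated correlation; adjusted p = 0.0663 without BaP 12 h replicate 1; adjusted p = 0.141 and a mean of -0.03 in place of -0.05 for genes leading 80% of pairs), and 7 rose and 17 fell at 24 h (adjusted p = 0.0770). The 214 G1 genes did not pass at 12 h (adjusted p = 0.398; median 0.01, mean -0.0088) or 24 h (0.217). No set differed in its BaP effect between times (adjusted p = 0.934 for each). In DMSO between 12 h and 24 h, 36 of the 200 S phase genes fell and 5 rose, with a median of -0.10 (camera adjusted p = 7.49e-05), a call that held with an estimated correlation (adjusted p = 0.0401). Of the 214 G1 genes 34 fell and 9 rose (adjusted p = 0.00107; adjusted p = 0.113 with an estimated correlation; adjusted p = 0.0574 without DMSO 24 h replicate 1), and the G2 and mitosis genes did not pass (0.436).

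A hypothesis is that fewer BaP-treated cells were in G2 or mitosis. It needs both calls to hold with an estimated correlation, and the larger adjusted p was 0.183, so the sets leave it open. Changes of this size may also reflect other regulation of a part of the genes, for which no test was run.

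The poly-A control mean was 9.91 in DMSO at 12 h, above 9.46 in BaP at 12 h, 9.38 in BaP at 24 h and 9.26 in DMSO at 24 h. The lowest DMSO 12 h array lay 0.294 above the highest array of the other 3 groups. Replicates of a group differed by up to 0.374, with replicate 1 higher in every group. The difference was 0.0106 in DMSO at 12 h, 0.302 in BaP at 12 h, 0.354 in BaP at 24 h and 0.374 in DMSO at 24 h. Part of these replicate differences may belong to the replicate number. Each group holds 1 array of either number, so the replicate number does not make the difference between group means. A step at or after hybridisation would move the hybridisation controls as well. Against DMSO at 12 h these moved by -0.368 (SE 0.223), -0.0571 (SE 0.181) and 0.131 (SE 0.151) of the poly-A shift in BaP at 12 h, BaP at 24 h and DMSO at 24 h. More control RNA added to the DMSO 12 h samples or less to the others, and a lower share of messenger RNA in total RNA in DMSO at 12 h or a higher one in the others, predict the same values and cannot be told apart, because no record of the amounts was used here. If the share of messenger RNA differed, the deposited values may hide a change common to most transcripts.

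The 18S probe sets of DMSO 24 h replicate 2 differed from replicate 1 by -1.77, -1.52 and -1.43, and 0 genes dropped as far. Its 3' minus 5' difference was 0.364 for beta-actin, within the range of 0.237 to 0.483 on the other arrays, and 0.0510 for GAPDH, where the others ranged from 0.00697 to 0.0448.

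For the model with time as a covariate, 34 splits of the 8 arrays into 4 and 4 could be fitted. Only 1, the real split, gave as many genes as its 1884, and the highest of the others gave 0. The other splits leave the BaP effect in the residual spread, which lowers their counts by construction, so these counts do not settle how many genes chance would give.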
